A study of Caenorhabditis elegans with 2 samples.

How the data were processed

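The series measured, by ChIP-seq with size-selected fragments of 150 to 350 bp per the labels, the genomic sites of an eGFP-tagged FKH-10 in late embryos, in 2 biological replicates of 1 group. The labels give the replicate numbers and call them biological, and the p-values below rest on peaks, not on replicates. The extraction protocol, the aligner, the peak caller and the threshold of the combined list are not given in the sources used here.

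Per the deposited lists of files, the authors aligned each replicate and a control to the ce10 and ce11 builds, called a relaxed peak list (peaks and background) for each replicate against the control and for both replicates together, and derived from these an optimal list thresholded by the irreproducible discovery rate (IDR), which compares peak ranks between replicates. Each deposited peak carries a signal, the height as the authors' caller gave it, whose scale is not given in the sources used here and which was used only to rank or describe peaks within a list. Each also carries the -log10 of a q-value in the deposited column of that name, which ran from 1.76 to 2.25 in the thresholded ce11 list and was not used to select peaks. The offset of the summit from the peak start gave summit positions. Every one of the 378 thresholded ce11 peaks was also a peak of the pooled relaxed list (7443 peaks), and the same 378 were those at or above a signal of 36.6, so the thresholded list is a signal threshold on the pooled list. The relaxed lists of replicates 1 and 2 held 27900 and 30000 peaks. That of replicate 2 held exactly 30000 on ce10 as well, so its length may be a preset limit on the list, which is not given in the sources used here. Most peaks of a list have 1 fixed width, 336 bp for 7383 of the pooled ce11 peaks, so a summit is mostly the middle of such an interval. The signal tracks and the alignments that the lists of files name were not used here, and read depth is unknown.

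Coordinates are 1-based on ce11, which has the chromosome lengths of WBcel235, and no ce11 peak ran past a chromosome end of that assembly. Genes came from Ensembl release 115 and sequence, tRNA isotypes and symbols of mitochondrial genes from the RefSeq annotation of the same assembly. The ce10 lists were used for counts and overlaps only, and positions were not converted between builds. Shares of nuclear summits were set against shares of the 100.3 Mb of nuclear bases with two-sided exact binomial tests for chromosomes, for windows from 1000 bp upstream to 500 bp downstream of protein-coding 5' ends, and for exons. Genes with a summit in that window were compared with all 19973 nuclear protein-coding genes by Fisher's exact test for 25 lists. The forkhead core was compared between windows of 100 bp to either side of the summit and flanks 500 bp away in a permutation test of 100000 draws that exchanged the 3 windows of each peak. Adjusted p-values are Benjamini-Hochberg values within each family, and a threshold of 0.05 was used. Around fkh-10 and unc-119, summits within 20 kb were counted and ranked among the counts of other genes. Genes are named by a rule: the nearest 5' ends within 2000 bp of the summits of the 20 highest peaks, fkh-10 and unc-119, and up to 4 members with the highest signal in each list that passed. These tests, lists, the rule and most alternatives were set before the data were examined.

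Chosen afterwards were the counts at RNA genes (within 100 bp), a scan of 35 kb windows in steps of 5 kb for dense groups of pooled summits, the extension of the 3 densest into stretches by joining summits at most 3 kb apart, the peak-free intervals, the words of 6 and 31 bases, the random shifts, the counts among the 20 highest peaks of each replicate, every alternative for tRNA and snoRNA genes, and every alternative that leaves out the stretches or the RNA gene peaks. Other settings chosen beforehand were other windows, gene models and overlaps, a GC-matched background (within 2 percentage points, 10 positions per peak), the upper part of the peaks by signal, the ce10 lists and the strongest peaks of each replicate alone. Leaving out peaks within 20 kb of fkh-10 and unc-119 removed 0 peaks and so tests nothing.

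The tests were checked on simulated data. With no effect, the promoter test on 358 peaks called 5 of 100 runs, the test for X 2 of 100, the motif test 0 of 20 and the ribosomal protein list test on 19973 genes 0 of 100. With 20% of peaks moved to 5' ends, 1.5 times as many peaks on X, the core planted at 20% of summits, or 8 list members added, they called 100 of 100, 76 of 100, 20 of 20 and 100 of 100. Simulated summits were placed at random, without the difference in G and C between real summits and flanks (45.5% against 36.1%). The motif runs thus do not show how that test performs on the real summits. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.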

Results

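Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which recovers the DNA bound by a chosen protein, was carried out on late embryos of the nematode Caenorhabditis elegans. Whole animals of mixed sex were used, from a strain labelled as carrying a transgene of fkh-10 with an eGFP tag. FKH-10 belongs to the forkhead family of transcription factors, and the question the labels give is where the tagged protein sits on the genome. The label's strain number and insertion number differ from each other, so the samples are called libraries labelled eGFP-FKH-10. The series held 1 group of 2 biological replicates, so the peaks were compared with the genome and between replicates, not with a second condition. The files used here give peaks without read counts, so the depth of each library is unknown and no interval below covers it. The 95% intervals are Wilson intervals that treat each peak as an independent count.

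The thresholded list held 378 peaks on the ce11 build, covering 124 kb, of which 358 lay on nuclear chromosomes and 20 on the mitochondrial genome. The highest peak of all, with a signal of 245 in the authors' units, had its summit in ATP6, a mitochondrial gene for a subunit of ATP synthase (position 2732 of the mitochondrial genome, 98 bp inside the 5' end). The next, with a signal of 229, lay in the mitochondrial large-subunit ribosomal RNA gene, and 14 of the 20 highest peaks were mitochondrial, at COX1, COX2, COX3, ND1, ND4, ND4L, ND5, CYTB and ATP6 as the nearest 5' ends. Among nuclear peaks the highest had its summit at 12303637 on chromosome V, inside frm-7 and the snoRNA gene C51F7.4, with a signal of 138. The nearest protein-coding 5' end was that of F55C5.17, 1096 bp away. It was followed by peaks in K05C4.2 on chromosome I (134), 291 bp upstream of the ribosomal protein gene rpl-3 on III (129), 544 bp upstream of ftt-2, which encodes a phosphoprotein-binding adaptor, on X (112.01), and 981 bp upstream of K05C4.9 on I (110). The median signal was 131 over the mitochondrial peaks and 46.0 over the nuclear ones. The height of the mitochondrial peaks came mostly from replicate 1, where 15 of the 20 highest peaks were mitochondrial, against 4 of 20 in replicate 2. In replicate 2 the highest mitochondrial peak had a signal of 58.2, below the highest nuclear one of 88.3. The ce10 version of the list held 374 peaks, also with 20 on the mitochondrial genome.

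The tagged gene itself had no peak. The gene fkh-10 (WBGene00001442) lies on chromosome I from 10163475 to 10165132, and no summit of the pooled relaxed list fell within 20 kb of it, against a median of 3 around other protein-coding genes. Of those other genes, 10.3% also had 0. The relaxed list of replicate 1 had 0 summits there against a median of 11, and that of replicate 2 had 1 against a median of 12, so that 0.381% and 0.446% of other genes had as few or fewer. Around unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the rescue marker named in the strain label, 3 pooled summits were found, the same as the median, and 49.2% of other genes had fewer. The peak-free interval that holds fkh-10, measured after its counts were seen, ran from 10129842 to 10196321 in replicate 1 (66.5 kb) and from 10129946 to 10182606 in replicate 2 (52.7 kb), where the median distances between neighbouring summits were 2.32 kb and 2.14 kb.

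Nuclear summits were not spread in proportion to chromosome length. Chromosome I carried 86 of 358 (24.02%, interval 19.9 to 28.7) on 15.03% of the nuclear genome, a 1.598-fold excess, and X carried 98 (27.4%, 23.01 to 32.2) on 17.7%, a 1.55-fold excess. Chromosomes II (35 summits, 9.78%), IV (47, 13.1%) and V (42, 11.7%) carried less than their length shares of 15.2%, 17.4% and 20.9%, and III (50, 13.97%) was close to its 13.7%. In two-sided exact binomial tests, adjusted over the 6 chromosomes by the Benjamini-Hochberg method, the adjusted p was 1.71e-05 for I, V and X, 0.00476 for II, 0.0369 for IV and 0.878 for III. The excess on I came from 1 stretch, from 14719496 to 14756350, which is 36.9 kb long and 4.55 Mb from fkh-10. It held 43 thresholded summits spread over pbs-5 (a proteasome subunit gene), K05C4.2, sol-2, K05C4.10, K05C4.9, K05C4.8, K05C4.4, K05C4.7, hmp-2 (the beta-catenin of cell junctions), K05C4.5, K05C4.3 and mtx-1. Weaker stretches lay on X from 16343862 to 16382038 (18 thresholded summits, over taf-3, nhr-28, ace-1 and sur-7) and on IV from 7026098 to 7060267 (3 thresholded and 37 pooled summits, over nhr-105 and klp-18 among others). In the stretch on I, 56 of the 60 pooled peaks had a width other than the usual one, against 0 in the stretches on X and IV. Without these 3 stretches, an alternative chosen after the data were examined, I carried 43 of 294 summits (14.6%, exact binomial adjusted p = 0.935), while X still carried 80 (27.2%, adjusted p = 0.000277). Without the tRNA, snoRNA and snRNA gene peaks as well, X carried 54 of 226 (23.9%, 1.35-fold, exact binomial adjusted p = 0.0364). There III also lay above its length share, with 44 (19.5%, 1.42-fold, adjusted p = 0.0364 in the same exact test). These were fewer than its 50 in the whole list, so its share rose from 13.97% through the smaller total. The deficits on II and IV lost their calls without the stretches (adjusted p = 0.184 and 0.339 in the same exact tests); in the strongest peaks of 1 replicate taken alone, II had an adjusted p of 0.152 without replicate 1 and IV one of 0.484 without replicate 2.

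**Figure D1:**
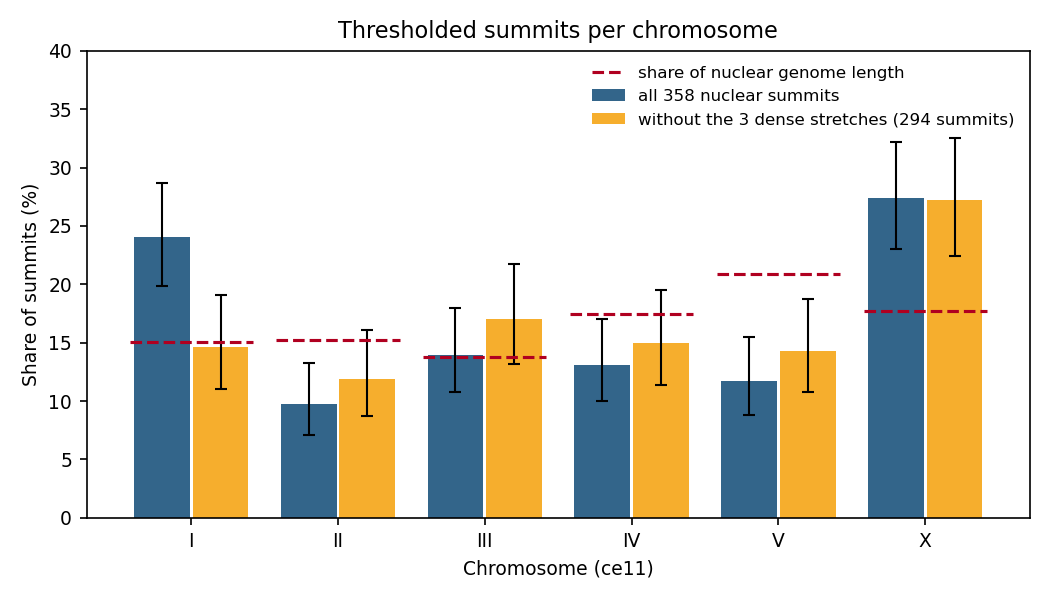
Share of thresholded nuclear summits on each chromosome (%, vertical axis) for all 358 summits and for the 294 outside the 3 dense stretches, with 95% Wilson intervals as bars and the chromosome's share of nuclear length as dashed lines. Chromosome I falls from 24.02% to 14.6%, and X stays at 27.4% and 27.2%.

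**Figure D2:**
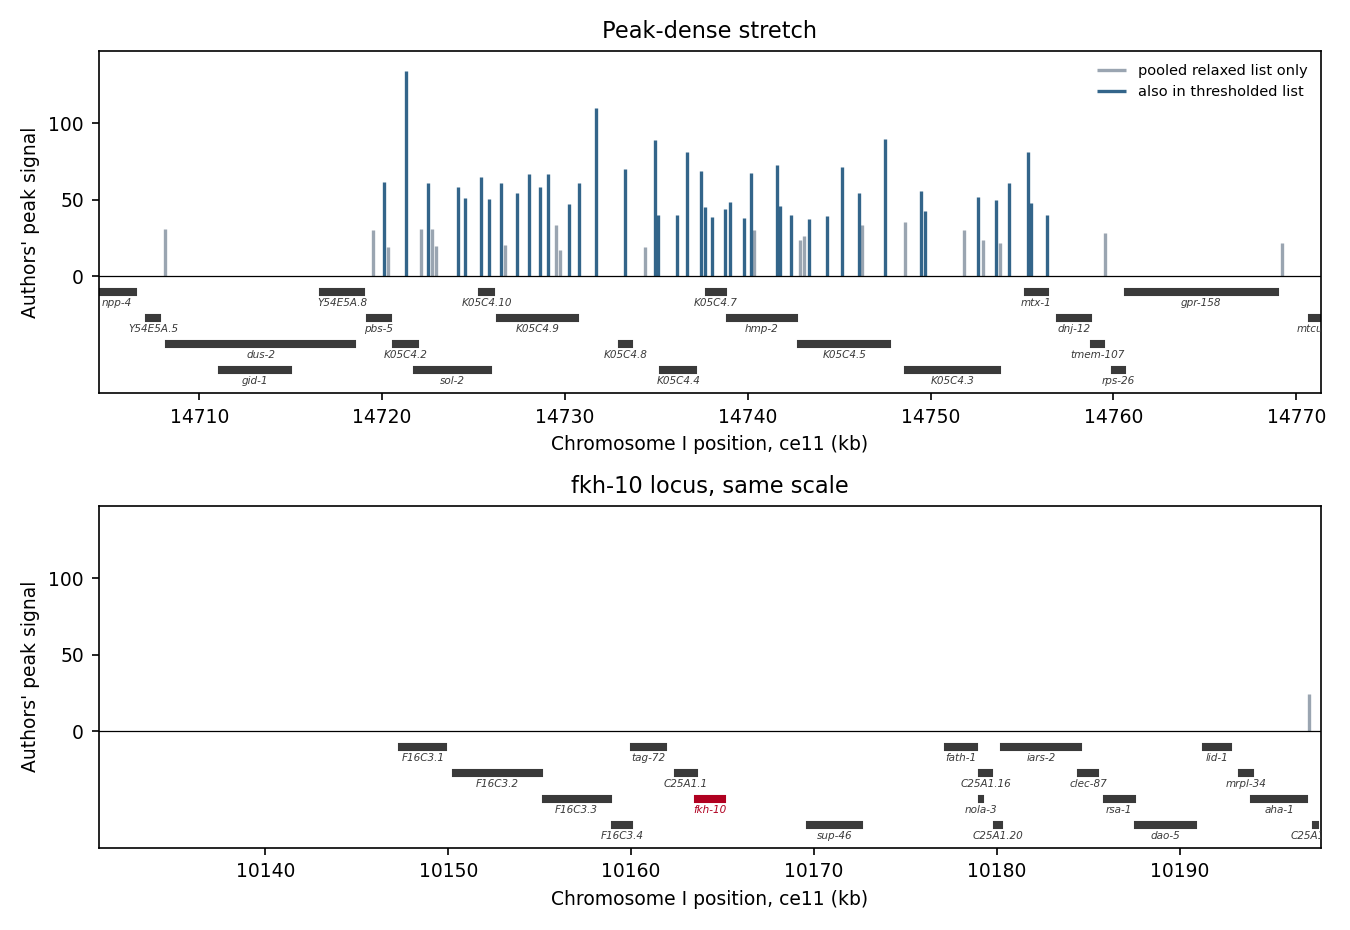
Pooled relaxed summits (vertical lines, height is the authors' signal) over protein-coding genes (boxes) in the dense stretch of chromosome I and, at the same scale, around fkh-10 (red box); positions are in kb on ce11, and blue lines are also in the thresholded list. The stretch holds 60 pooled summits between 14719496 and 14756350, and none lies within 20 kb of fkh-10.

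Summits favoured the 5' ends of protein-coding genes and avoided exons. Within 1000 bp upstream to 500 bp downstream of a 5' end lay 156 of the 358 nuclear summits (43.6%, interval 38.5 to 48.8), against 26.4% of nuclear bases, a 1.65-fold excess (two-sided exact binomial p = 2.69e-12). Protein-coding exons held 46 summits (12.8%, 9.77 to 16.7) against 29.5% of bases (exact binomial p = 1.28e-13), and outside the 3 dense stretches they held 18 of 294 (6.12%). By chromosome, outside the stretches, the promoter share was highest on I (27 of 43, 62.8%) and III (27 of 50, 54%), 40.9% on IV and 33.8% on X, with exact binomial adjusted p of 8.49e-07, 2.74e-05, 0.0316 and 0.0285, while on II (34.3%) and V (45.2%) it was not past the threshold (adjusted p = 0.579 and 0.0816 in the same exact tests). Differences between chromosomes were not tested.

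Genes for small structural RNAs, examined after the highest peaks had been seen, took a large part of the list. No untagged strain was analysed here, so summits at these or at protein-coding genes cannot be assigned to binding of FKH-10 from the peak list alone. Within 100 bp of a nuclear tRNA gene lay 40 summits (11.2% of 358, interval 8.31 to 14.9), where such bases make up 0.164% of the nuclear genome, and within 100 bp of a snoRNA gene, whose RNAs guide modification of ribosomal RNA, lay 25 (6.98%, 4.77 to 10.1) on 0.116% of bases. The snoRNA peaks were among the highest, with a median signal of 55.6, and included those at ZK994.7 inside pxn-1 (chromosome V, summit 8500579, signal 96.7), ZK265.10 (I, 8259569, 94.3) and T02E1.9 (I, 8224415, 80.8). There were 2 summits at miRNA genes, where 0.259 were expected. There were 3 summits at snRNA genes, of which 2 lay at the spliced-leader genes sls-2.1 and sls-2.2, and 77 at genes annotated as other ncRNA (21.5% on 2.34% of bases). In contrast, 0 summits lay at piRNA genes (2.21% of bases, which gave 7.91 as the expected number) and 2 at pseudogenes (12.97 expected). A summit could count in several of these classes, so the 77 are not all additional to the tRNA and snoRNA summits. When nuclear summits were divided into exclusive classes, 13 (3.63%) remained as other ncRNA. Summits in the dense stretches, at tRNA, snoRNA or snRNA genes, or in promoter windows had been assigned to those classes first. Two-sided exact binomial tests over 9 gene classes gave adjusted p of 4.19e-58 for tRNA, 1.49e-35 for snoRNA, 0.000827 for snRNA, 0.0363 for miRNA, 7.5e-49 for other ncRNA, 0.00122 for piRNA and 0.000752 for pseudogenes.

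**Figure D3:**
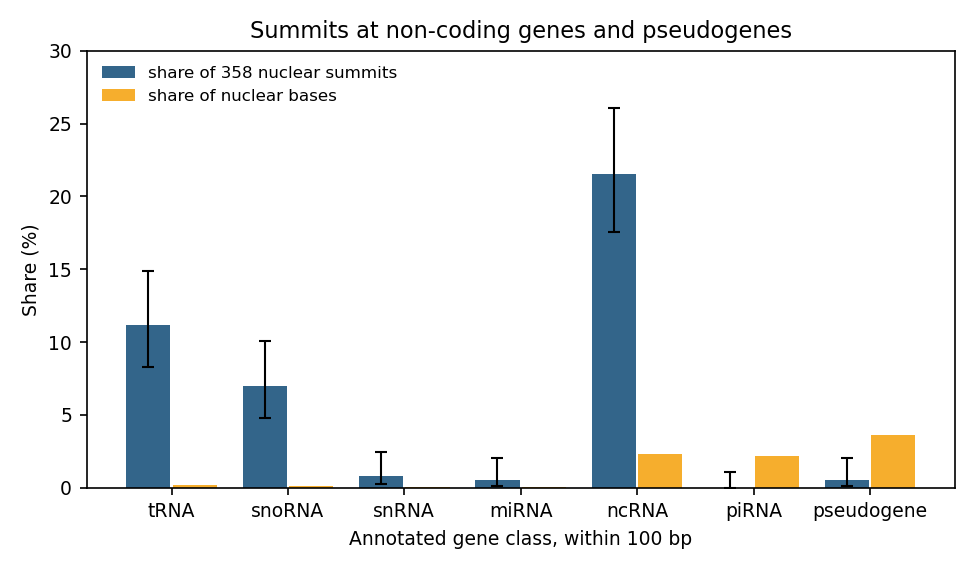
Share of the 358 nuclear summits within 100 bp of annotated non-coding genes and pseudogenes, by class (%, blue, with 95% Wilson intervals) beside the share of nuclear bases in the same windows (orange). A summit can count in several classes. tRNA genes stand at 11.2% of summits and 0.164% of bases, and piRNA genes at 0 summits.

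Among 25 gene lists fixed before the data were examined, ribosomal protein genes stood out. A summit lay in the promoter window of 7 of 81 (8.64%), against 195 of 19973 protein-coding genes overall (0.976%), with an odds ratio of 10.5 (Fisher's exact test, adjusted p = 0.000359). The highest were at rpl-3 (signal 129), rpl-20 (83.5), rpl-15 (75.0) and rpl-12 (46.1), and all 7 had their summit 4 to 966 bp from the 5' end. For rpl-20 the 5' end of another gene lay nearer to the summit (178 bp, against 284 bp). With 1 gene per peak 6 of the 81 had a summit (odds ratio 11.1, exact adjusted p = 0.00111). The core histone list, which also holds linker histone genes, had 4 of 60 (odds ratio 8.20, exact adjusted p = 0.0351). These were his-67 and his-68, which share 1 peak between them (67.97), his-37 (45.4) and the linker histone gene hil-7 (40.3). By a rule set beforehand, core histone genes that are near-identical copies count as uncertain, and the histone result carries that limit. Heat shock and unfolded protein genes had 3 of 34 (odds ratio 11.4, exact adjusted p = 0.0366): hsp-60, a mitochondrial chaperonin (46.9), dnj-12 (39.8) and xbp-1, a regulator of the unfolded protein response (39.1). The heat shock list lost its call in 7 of 10 alternatives, among them those without the dense stretches (the summit of dnj-12 is the last of that on I; odds ratio 8.61, exact adjusted p = 0.306), without replicate 2 (4.96, 0.676), within 500 bp either side (6.36, 0.607), from 2000 bp upstream (8.33, 0.0850) and with 1 gene per peak (5.62, 0.607). The histone list lost it in 3 of 10, among them without replicate 1 (odds ratio 6.93, exact adjusted p = 0.0997) and with 1 gene per peak (7.73, 0.149). Among the upper 189 peaks by signal none of the 25 lists passed, and the ribosomal list had an odds ratio of 10.3 with an exact adjusted p of 0.138, in fewer peaks.

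The lists for tissues and developmental regulators held few summits or none, and none of the other 22 lists passed the threshold (lowest exact adjusted p 0.630). Mitochondrial respiration genes (cox-5A and cox-5B) and translation factor genes (iff-2 and eif-3.C) had 2 each, of 56 and 63 members (without replicate 2 the respiration list had 4 of 56, odds ratio 9.64, and passed with an exact adjusted p of 0.0171), and homeobox genes (ceh-38 and ceh-39, of 94) and nuclear hormone receptors (nhr-14 and nhr-255, of 274) also had 2 each. The insulin signalling, V-ATPase, Wnt pathway, proteasome, ciliated sensory neuron, cuticle collagen and neuropeptide lists had 1 member each: ftt-2, vha-13, hmp-2, pbs-5, klp-20, col-85 and ins-39. No summit lay at any of the 15 forkhead genes or at the bHLH (38), epidermal (42), intestinal (45), body wall muscle (48), pharyngeal (39), pan-neuronal (47), glial (23), germline and P granule (47), basement membrane (24) or Notch pathway (29) genes. With 0.976% of genes holding a summit, fewer than 1 gene was expected in each of these 11 lists, so their depletion was not detectable. These members were named after their values were seen.

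The forkhead recognition core was rarer at summits than beside them. The core RTAAAYA (R is A or G, Y is C or T), searched on both strands within 100 bp, occurred at 9.50% of the 358 nuclear summits (interval 6.88 to 12.98) and in 18.7% of windows of the same width 500 bp to either side, a difference of -9.22 percentage points (two-sided permutation test, p = 0.00016). Summit windows were richer in G and C, at 45.5% (SD 7.24 across peaks) against 36.1% (SD 5.51) in the flanks, with a higher value at 298 of 358 summits (permutation p = 1e-05, the smallest that 100000 permutations can give). Against 3580 random nuclear positions matched on GC content, 9.92% of which held the core, the difference was -0.419 points (Fisher's exact test, p = 0.853). All 209 other arrangements of the same letters were also rarer at summits than in flanks, and 53.1% of them were more depleted than the forkhead core. In the strongest peaks of replicate 1 alone the difference was -4.10 points (permutation p = 0.0847), and for the single core GTAAACA it was -1.82 (permutation p = 0.101). Peak height showed no detectable relation to the core: it occurred at 10.6% of the upper and 8.38% of the lower 179 peaks by signal (permutation p = 0.588).

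**Figure D4:**
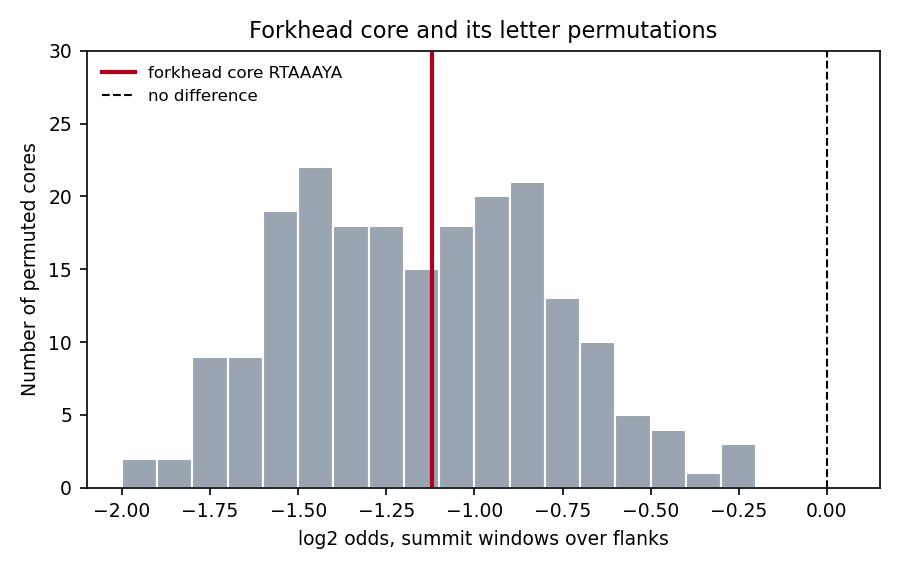
Number of arrangements of the letters of the forkhead core (vertical axis) by log2 odds of occurring in summit windows over flanks (horizontal axis), with the forkhead core as a red line and no difference as a dashed line. The core stands at -1.12, near the median of -1.15 of its 209 permutations.

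Most thresholded peaks overlapped one of the strongest peaks of each replicate, but the replicates shared less with each other. The thresholded peaks were the highest of the list called on both replicates together, so overlap with each replicate is partly built in. Of the 378 thresholded peaks, 263 (69.6%, interval 64.8 to 73.9987) overlapped one of the 378 strongest peaks of replicate 1 by at least 1 bp, 245 (64.8%, 59.9 to 69.5) one of those of replicate 2, and 165 (43.7%) one in both. Among nuclear peaks, 149 of the 354 strongest of replicate 1 (42.1%) overlapped one of the 366 strongest of replicate 2, where 100 random shifts along the chromosomes gave 0.254% on average. Both replicates were called against the same control, and the overlap that a shared control alone would give was not measured. Over the whole relaxed lists the share was 31.6%, against 19.6% after shifting. Within the thresholded list, signals of the 374 peaks found in both replicates were weakly related, with a Spearman's rho of 0.162 across peaks, which are not independent replicates and were chosen for high pooled signal. Over the 354 nuclear peaks among them rho was 0.146, and over the 293 nuclear peaks outside the dense stretches it was 0.0780. Some neighbouring thresholded peaks were matched to the same replicate peak. The dense stretch on I supplied 40 of the strongest 378 peaks in replicate 1 and 51 in replicate 2, tRNA genes 29 and 34, snoRNA genes 21 and 25, and the mitochondrial genome 24 and 12.

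**Figure D5:**
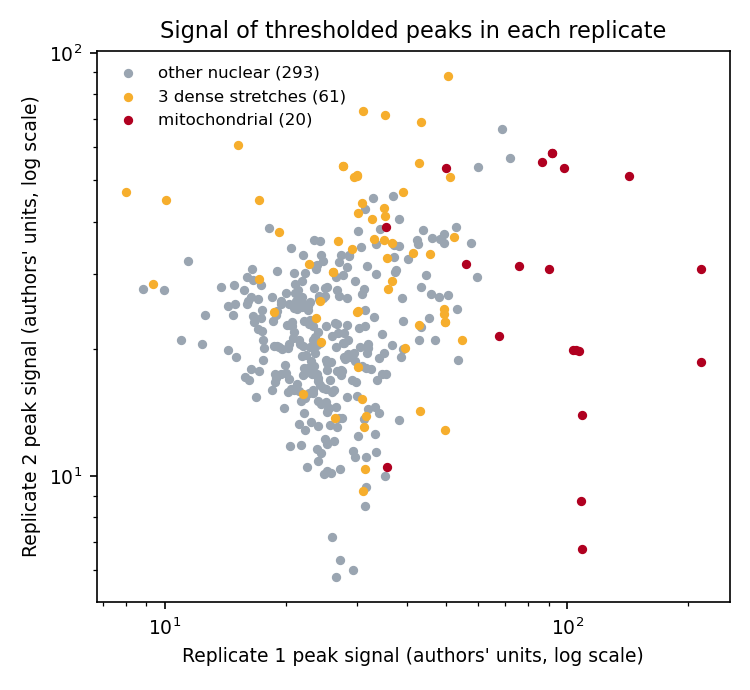
Authors' peak signal in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales, for the 374 thresholded peaks with a peak in both relaxed lists, coloured by whether they are mitochondrial, in the 3 dense stretches or elsewhere. The points show little relation (Spearman's rho 0.162), with most mitochondrial peaks to the right.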

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

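Tests of the peak-free interval against the control library, of the stretch on chromosome I in single replicates and of transcription factor genes in dense windows were chosen only after the results were seen. The test of repeated sequence as the whole reason for the interval was added after a first test of repeats left the matter undecided, before its own value was seen.

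Peaks on the mitochondrial genome drew attention because a nuclear transcription factor was the target and the design's comparisons concern nuclear chromosomes. There were 20 such peaks in the thresholded list (5.29%, Wilson interval 3.45 to 8.03), or 1.45 per kb of mitochondrial genome against 3.57 per Mb of nuclear genome. Of the pooled relaxed mitochondrial peaks 87.0% passed into the thresholded list, against 4.82% of nuclear ones. Neighbouring mitochondrial summits lay a median of 684 bp apart, with 18 in protein-coding and 2 in ribosomal RNA genes. No explanation of these peaks was tested.

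A scan of the pooled relaxed list in 35 kb windows, which the planned comparisons do not use, drew attention to 3 windows, with 56 summits on chromosome I, 42 on X and 36 on IV, where the median window held 2 and the 99th percentile was 9. Repeated sequence was argued against (5.66% of 31-base words in the stretch on I occurred again, against 8.73% over the nuclear genome). Chance in 1 of the immunoprecipitated libraries was argued against too, since the stretch was the densest window in 2 of 2 replicates. The 3 stretches held 13 of the 20 highest peaks of replicate 2 and 0 of 20 in replicate 1. In replicate 1, 15 of those 20 were mitochondrial, and the best nuclear rank in the stretch on I was 6. Chance in the control that both replicates share stays open. Clustered binding sites of 1 protein stay open. The coding share of summits in the stretch on I lay above the rate elsewhere, scaled by the coding share of bases (one-sided exact binomial p = 0.00382). In the stretches on X and IV together it did so too (exact p = 0.0213), although for IV alone the exact p was 0.203. Summits packed this densely approach the coding share of bases whatever the cause, so the test cannot decide. Extra copies of the stretch in the sequenced DNA stay open, since summits on I fell in coding sequence about as often as bases did (43.3% against 38.4%, two-sided exact binomial p = 0.429), a result that 60 summits could also give by lack of power. DNA of strains with other tagged transcription factors may account for the windows elsewhere, since 5 of the 10 densest held a transcription factor gene (random sets of 10 windows had a median of 1), but binding near such genes would give this as well and was not tested. The densest window, that on chromosome I, held no gene of the transcription factor lists.

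The interval without peaks around fkh-10 lacks the rise that extra transgene copies in the immunoprecipitated DNA but not in the control would give. The percentile of the pooled count was 0 at fkh-10, where 10.3% of other genes also had 0 summits, and 49.2 at unc-119. Copies that the control carried as well could cancel, so these values do not show that the immunoprecipitated DNA lacked them. Repeated sequence as the whole reason for the interval was argued against. Of the 50 kb windows with at least as many repeated words, 0.704% held no replicate 1 summit. A first test of repeats was undecided, at 8.92% of words against 8.73% over the genome. Replicate 1 had 3 intervals at least as long and replicate 2 had 6, counting that with fkh-10. Those without fkh-10 had at least 90.4% repeated words in replicate 1 and at least 63.6% in replicate 2. The interval with fkh-10 had 8.59% and 8.92%, so it alone lay in mostly unrepeated sequence. Extra transgene copies in the control library may have lowered the calls there, but no value decides this: that at most 0.486% of nuclear bases lay in intervals as long in either replicate (12.1% in the sparser pooled list) restates the low count that prompted the test. If the control came from a strain with the fkh-10 transgene and the immunoprecipitated DNA from a strain with another, this interval and the dense stretch on I could share an origin; neither that nor a loss of this DNA was tested, and the control library was not analysed here. No biological explanation of this interval was tested.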

How the results depend on the processing

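Alternatives without the dense stretches or the RNA gene peaks, and all those for tRNA and snoRNA genes, were chosen after the data were examined. Of 142 alternative values, 38 changed direction, crossed the threshold or moved beyond the spread. The 142 include the setting without peaks near fkh-10 and unc-119, which removed no peaks and so could only leave values the same. The shares on X (23.9% to 30.8%), on V (9.47% to 14.3%), in promoter windows (33.8% to 56.1%), at tRNA genes (6.15% to 13.6%) and at snoRNA genes (1.397% to 10.7%) kept their direction in the alternatives run, and their side of the threshold where a test was run (none was for the ce10 list).

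Without the dense stretches the share was 14.6% on I, 11.9% on II and 14.97% on IV, and without these and the RNA gene peaks it was 16.4% on I, 11.5% on II, 19.5% on III and 15.04% on IV; by construction, the stretches hold 43 summits on I, 0 on II and 3 on IV, so the shares on II and IV rose because the total fell from 358 to 294. In the upper part of the signal values (189 peaks by construction), III had 10.7% and 0 gene lists passed, with fewer peaks tested. With 1 gene per peak 1 list passed. Without replicate 1 or replicate 2, the share was 10.7% to 12.3% on II, 12.1% to 12.8% on III and 11.7% to 15.8% on IV, and the motif difference was -11.3 to -4.10 points. That difference was -1.82 for the single core and -0.419 against GC-matched positions. The difference by height was -2.79 points for the single core. The cause was not tested for these.

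The share of thresholded peaks found among the strongest of replicate 1 and of replicate 2 was 63.5% and 58.7% with an overlap of 0.5 of both lengths, 63.8% and 59.8% with summits within 100 bp, 85.98% and 81.7% in 756 peaks, and 99.7% and 99.2% in the full lists, which follows from the stricter or looser criteria. Leaving out peaks near fkh-10 and unc-119 removed 0 peaks, so it shows nothing of stability. No paired analysis was possible because there is 1 group. The depth is unknown, so its limits could not be given.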

Other observations

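The tests on tRNA genes, base composition and 6-base words were chosen after the results were seen; the test of permuted cores was planned.

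Among nuclear tRNA genes, those on X had a summit within 100 bp more often than those on autosomes. It was 29 of 276 on X (10.5%) and 14 of 336 on autosomes (4.17%; Fisher's exact test, two-sided p = 0.00247), and 26 of the 40 summits at tRNA genes lay on X. The highest was at a leucine tRNA gene (WBGene00000308, X, 13665555 to 13665673, signal 85.5). No isotype stood apart from the others (lowest exact adjusted p 0.986 over 22 isotype classes), with 5 of 39 leucine, 4 of 34 alanine, 4 of 41 glutamate and 3 of 20 methionine tRNA genes holding a summit. Of the 25 summits at snoRNA genes, 0 lay on X, which holds 33 of the 346 snoRNA genes (9.54%). Of these 25 summits, 12 lay inside a protein-coding gene, and 18 were at or above the median nuclear signal.

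Among the 226 nuclear peaks outside the dense stretches and the tRNA, snoRNA and snRNA genes, short repeats of G and A marked the summits. The word GAGAGA, read on either strand, occurred within 100 bp of 40.7% of summits and in 8.19% of flanks (Fisher's exact test, adjusted p = 1.04e-19 over 2080 words). CGCGCA occurred at 23.9% and 2.21% (exact adjusted p = 6.62e-16), and AAAATT was rarer at summits, at 28.8% against 63.5% (exact adjusted p = 4.68e-15). Of all words, 295 were more frequent and 240 less frequent at summits past the threshold, and both flanks of a peak were counted as independent windows. These summit windows had 46.7% G and C against 36.2% in flanks, and the words were not compared with GC-matched positions.

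The lower frequency of the forkhead core at summits may reflect base composition. Of the permuted cores 53.1% were more depleted than the core itself, and the difference against GC-matched positions was -0.419 points. Binding of FKH-10 through its core at a minority of summits stays open, as no second group or untagged strain was analysed here. No biological explanation of this depletion was tested.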
